A study of Mus musculus with 8 samples.

How the data were processed

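RNA was measured in 8 libraries of R1 cells, a mouse embryonic stem cell line grown in serum with LIF, by RNA sequencing. The libraries form 4 groups of 2, named by day: D1, D3, D8 and D10. Per the labels, ML-792, an inhibitor of the SUMO E1 enzyme, was given in 2 exposures of 48 h, from D1 to D3 and from D8 to D10, at a dose labelled 2.5 mM. D1 and D8 are labelled control, and D3 and D10 are labelled ML-792. The title of D1 replicate 2 gives D1 while its time tag gives day 0, and it was kept in the D1 group. The labels call the molecule polyA RNA, whereas the extraction text describes a stranded total RNA kit with removal of ribosomal RNA. No label says whether the replicates of a group are separate cultures, so the p-values measure only the spread between these samples.

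The authors deposited raw counts, that is, whole numbers of reads per Ensembl gene with no normalization. Per the labels, reads were made with bcl2fastq 2.17.1.14, aligned with STAR 2.5.0a to the mouse build mm10 and counted with featureCounts. The featureCounts version, the annotation release, and the settings for strand and for reads that match several places are not given in the sources used here. Genes that overlap on opposite strands, and members of multi-copy families, are therefore less certain than the rest. The table holds 36920 genes, of which 1438 had no read in any library. Symbols, biotypes and coordinates on mm10 (GRCm38) were taken from the GENCODE M21 annotation by Ensembl identifier. A symbol was found for 36901 identifiers and none for 19.

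The libraries held 21040992 to 40835518 reads in genes. Genes were kept by edgeR's filterByExpr with the 4 groups, which left 19173 genes tested in every comparison. Levels are in CPM, edgeR's unit of reads scaled to a common library total, after TMM scaling, and log2 CPM used a prior count of 2. Group levels are mean CPM with the SD of the 2 libraries. The SDs and SEs include the spread between libraries. Floors cover counting error only, and reads without molecular identifiers are not independent molecules. Where a gene had 0 reads in a group, its fold was bounded with a floor of 3 reads over the group.

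The comparisons were D3 with D1, D10 with D8, D8 with D1, D8 with D3 and D10 with D1, the difference between the responses to the second and the first exposure, and all 4 ML-792 libraries with all 4 control libraries. The first 6 were contrasts of 1 quasi-likelihood fit of the 4 groups in edgeR 4.0.16, with 4 residual degrees of freedom and a biological coefficient of variation of 19.6%. The last was a separate fit with treatment as its term. Tests were 2-sided. P-values were adjusted by Benjamini-Hochberg over the 19173 genes, and a gene was called at an adjusted p under 0.05. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. The analysis was run in R 4.3.3.

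The gene lists, the comparisons and the rule for named genes were fixed before the data were examined. The 22 lists were 2-cell-like genes, naive pluripotency, general pluripotency, formative and primed epiblast, primitive streak and mesoderm, primitive and extraembryonic endoderm, trophoblast, neural ectoderm, Hox genes, germline genes, imprinted genes, the SUMO pathway, heterochromatin and silencing factors, interferon response, p53 targets, cell cycle, integrated stress and unfolded protein response, heat shock, signalling read-outs of Wnt, Nodal, FGF and BMP, fibroblast markers, blood and endothelial markers, and mitochondrial transcripts. Each list was tested with camera of limma 3.58.1 on log2 CPM, with a preset correlation of 0.01 and adjustment over the 22 lists of a comparison. Camera was repeated with the correlation estimated from the data, and fry was run beside it. Member counts are given over all genes tested and adjusted over the list alone.

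Genes were named by a rule. Per comparison it took the 8 largest rises and 8 largest falls among genes with an adjusted p under 0.05, a mean CPM of at least 1 and no overlap between the library values, leaving out predicted-gene names. From each list it took up to 4 called members with the largest change. Uba2, Sae1, Zscan4c, Duxf3, Zfp352, Pou5f1, Sox2, Nanog and Sox17 were included whatever their value. A part of these genes is named.

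The procedure was tested on simulated data with the same depths and spread, in which 200 of 19173 genes were changed. In the comparisons of 2 groups, 57.6% to 69.7% of genes changed 4-fold were recovered, and 14.9% to 35.8% of those changed 2-fold. Of the calls in those comparisons, 8.93% to 11.1% were false. The pooled treatment fit recovered 84.8% and 46.3%, with 7.07% false. The difference between responses recovered 42.4% and 0%, with 3.45% false. With the preset correlation, a simulated list of 30 genes changed 1.5-fold was called in all 7 comparisons, with 0 of the other lists called. The simulated genes varied independently and the lists were random. The simulation therefore cannot show how often camera calls a list whose genes move together.

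Alternatives tried were size factors by the RLE method, DESeq2 1.42.0, no filter on low counts, a stricter filter (CPM of at least 1 in at least 2 libraries and a mean of at least 50 reads), an adjusted p under 0.01, a 2-fold minimum, the replicate number as a block, a fit of only the groups compared, the round of treatment as a covariate, leaving out mitochondrial and ribosomal genes and the 50 most abundant genes, and leaving out each library in turn. In a fit that leaves out 1 library, the remaining library of its group is assumed to vary like the other groups. A correction for trends with GC content and gene length was added after the data had been seen. No library was left out of the comparisons as reported.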

Results

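RNA sequencing gave read counts for 8 libraries of R1 mouse embryonic stem cells, 2 at each of D1, D3, D8 and D10. D1 preceded the first 48 h exposure to ML-792 and D3 closed it, and D8 and D10 stood in the same places for the second. D8 came 5 days after D3. Reads in genes numbered 21040992 and 32610314 in the D1 libraries, 23551283 and 28215299 at D3, 30527519 and 33036253 at D8, and 24281905 and 40835518 at D10. The log2 CPM of the 2 libraries of a group correlated across genes at r = 0.988 for D1, 0.9874 for D3, 0.9808 for D8 and 0.9822 for D10, and genes are not independent replicates. The first principal component held 61.1% of the variance and separated the 4 ML-792 libraries from the 4 control libraries, and the second held 15.6%. On the second, replicate 1 lay above replicate 2 in each group (53.2 and 18.9 at D1, 16.2 and -0.261 at D3, 5.42 and -54.6 at D8, 0.989 and -39.8 at D10). D8 replicate 2 stood apart in composition. The noncoding RNA Rn7sk took 3.41% of its reads against 2.19% to 2.76% in the other libraries, and Malat1 took 0.0971% against 0.194% to 0.421%. Across 10569 coding genes, its deviation from the mean of all libraries rose with GC content at a Spearman rho of 0.643, against -0.417 to 0.102 in the other libraries. That rho was higher in replicate 2 than in replicate 1 in each group (-0.186 and 0.102 for replicates 1 and 2 at D1, -0.368 and -0.333 at D3, 0.0708 and 0.643 at D8, -0.417 and 0.0617 at D10). The main fit held no term for the replicate number.

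D3 was compared with D1 to ask how the transcriptome differed after 48 h of ML-792. The labels name no library at D3 or D10 without ML-792. The inhibitor and the 48 h of further culture therefore change together in both exposures. Genes of the 2-cell embryo rose most plainly. Zscan4c, which marks the transient 2-cell-like state of stem cell cultures, went from 18.6 ± 8.27 CPM to 432 ± 295 CPM (SD, n = 2), a log2 fold change of 4.55 ± 0.53 (SE, adjusted p = 0.0026). Duxf3, the transcription factor gene that switches on such genes, rose by 3.8 ± 0.49, the deubiquitinase gene Usp17le by 4.76 ± 0.55 and the zinc finger gene Zfp352 by 2.24 ± 0.48 (adjusted p = 0.019). Large rises outside that group included the cytochrome P450 gene Cyp2b23, which reached 72.5 ± 33.9 CPM (5.96 ± 0.44), and the protease inhibitor gene Serpina3m, from 0.086 ± 0.054 to 23.6 ± 5.95 CPM. Among the falls, the transglutaminase gene Tgm2 went from 38.8 ± 18.1 to 2.58 ± 0.194 CPM (-3.91 ± 0.41, adjusted p = 0.002). On the log2 scale, the homeobox gene Nkx6-3 fell by 5.91 ± 0.46 and the POU-domain gene Pou2f3 by 4.42 ± 0.46. Zscan4, Duxf3, Usp17l and Serpina3 are multi-copy families, so the reads of single members are uncertain. On mm10, Zscan4c (ENSMUSG00000054272) lies on chromosome 7 from 11005745 to 11010547, and Cyp2b23 (ENSMUSG00000040650) on chromosome 7 from 26665227 to 26686437.

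In the same comparison, 34 of the 36 measured genes of the 2-cell-like list rose and 0 fell, and 36 rose when adjusted over the list alone, with a median log2 fold change of 3.56 (camera adjusted p = 8.1e-20, and 0.53 with an estimated correlation). Of the 23 naive pluripotency genes 9 fell and 0 rose (12 and 1 adjusted over the list alone, 5.9e-05, and an adjusted p of 0.53 with an estimated correlation), led by the growth factor gene Fgf4 (-2.05 ± 0.17), the kinase co-activator gene Tcl1 (-2.14 ± 0.27), Prdm14 (-1.37 ± 0.28) and Gbx2 (-1.34 ± 0.19). Nanog (-0.76 ± 0.24, adjusted p = 0.07), Pou5f1 (-0.46 ± 0.15, adjusted p = 0.086) and Sox2 (0.1 ± 0.16, adjusted p = 0.74) did not pass. Nanog was called by DESeq2 (0.031) and without either D10 library (0.013 each), and Pou5f1 came just under the threshold without D8 replicate 2 (0.05 when rounded). Among 18 formative and primed epiblast genes 6 rose and 1 fell (6 and 3 adjusted over the list alone, 0.018, and an adjusted p of 0.53 with an estimated correlation), with Wnt8a at 3.71 ± 0.48, Zic2 at 2.66 ± 0.22 and the DNA methyltransferase gene Dnmt3a at 1.56 ± 0.14. Of 30 p53 targets 15 rose and 1 fell (22 and 1 adjusted over the list alone, 2.6e-06, and an adjusted p of 0.53 with an estimated correlation). Pmaip1, which encodes a pro-apoptotic BH3-only protein, rose by 1.79 ± 0.21 and the kinase gene Plk2 by 1.93 ± 0.31, while Gdf15 fell by 1.66 ± 0.27. Of 34 cell cycle genes 5 fell and 0 rose, both over all genes and adjusted over the list alone (0.018, and an adjusted p of 0.53 with an estimated correlation), with Ccne1 at -0.89 ± 0.17 and Ccnb2 at -0.73 ± 0.14. Of 25 genes of the integrated stress and unfolded protein response 5 fell and 3 rose (9 and 3 adjusted over the list alone, 0.027, and an adjusted p of 0.53 with an estimated correlation), with Nupr1 at -2.54 ± 0.36 and Trib3 at -1.34 ± 0.24. Of 27 primitive and extraembryonic endoderm genes 4 rose and 0 fell, also when adjusted over the list alone, among them Fgfr2 (2.59 ± 0.25) and Gata6 (1.35 ± 0.25). Of 26 signalling read-outs 4 rose and 2 fell (7 and 2 adjusted over the list alone), with Spry2, a feedback inhibitor of FGF signalling, at 1.19 ± 0.12. The last pair of lists was called just under the threshold (0.05 when rounded), each at an adjusted p of 0.79 with an estimated correlation.

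Camera called 8 of the 22 lists between D3 and D1. With an estimated correlation none passed, and the same held for each of the 50 list calls in the 7 comparisons. That correlation is estimated from few residual degrees of freedom, 4 in the fit of the 4 groups. The simulated lists were tested with the preset correlation only. How often the estimated one would find a real change is therefore not known, and its losses do not show that a list was unchanged. Without 1 library, the call was lost for formative and primed epiblast (adjusted p = 0.078 without D1 replicate 1 and 0.084 without D3 replicate 2), cell cycle (0.13 without D3 replicate 2), the integrated stress list (0.078 without D1 replicate 1) and primitive and extraembryonic endoderm (0.33 without D1 replicate 1 and 0.35 without D3 replicate 2). Endoderm and signalling read-outs were also lost with RLE size factors (0.052 for each) and without the low-count filter (0.069 for each), and the integrated stress list with the correction for GC content and length, added after the data were seen (0.077). For signalling read-outs the call was lost without D1 replicate 1 (0.13), D3 replicate 1 (0.067), D3 replicate 2 (0.079), D10 replicate 1 (0.058) or D10 replicate 2 (0.053).

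Lists that camera did not call between D3 and D1 held single genes that changed. Imprinted genes had 10 higher and 2 lower of 46 (adjusted p = 0.076), with Magel2 at 3.66 ± 0.48, Peg10 at 1.42 ± 0.27 and Phlda2 at -1.78 ± 0.21. The interferon response had 3 higher and 6 lower of 29 (0.076), with the MHC class I activator Nlrc5 at 2.15 ± 0.37, Xaf1 at -3.63 ± 0.41 and Ifitm1, of a multi-copy family, at -2.61 ± 0.35. Germline genes had 8 higher and 3 lower of 40 (0.61), with the meiotic gene Sycp1 at 1.55 ± 0.26. Neural ectoderm had 4 higher and 2 lower of 15 (0.29), with En2 at 2.28 ± 0.32. Trophoblast had 2 higher and 3 lower of 24 (0.63), with Tead4 at -1.99 ± 0.2. General pluripotency had 2 higher and 2 lower of 24 (0.76), with Dppa2 at 0.58 ± 0.15 and Dppa5a at -1.48 ± 0.23. Primitive streak and mesoderm had 4 higher and 1 lower of 23 (0.37). Heterochromatin and silencing factors had 1 higher of 35 (0.76), Atf7ip (1.9 ± 0.17, 59.8 ± 12.7 to 223 ± 10.6 CPM), a cofactor of the histone methyltransferase Setdb1. The SUMO pathway had 1 lower of 29 (0.67), the SUMO protease gene Senp3 (-0.68 ± 0.14). The genes of the SUMO E1 subunits, Uba2 (-0.09 ± 0.13, adjusted p = 0.7) and Sae1 (0.07 ± 0.15, adjusted p = 0.81), did not pass. Heat shock had 1 higher of 16 (0.95). Fibroblast markers had 2 higher of 15 (0.16), one of them Twist2, which had 0 reads at D1 and was at least 4.96-fold higher at D3. Hox genes (0 of 19, adjusted p = 0.16), blood and endothelial markers (0 of 11, 0.87) and mitochondrial transcripts (0 of 7, 0.15) held no called gene by edgeR. The mitochondrial list says little of RNA quality, since mt-Nd3, mt-Co2, mt-Co3 and mt-Atp6 had 0 to 6 reads in each library, where mt-Co1 had 133884 to 301084. Camera's direction was down for general pluripotency (median 0.07, mean -0.08) and for heat shock (median 0, mean 0.14).

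Over all genes, 1518 were higher and 978 lower at D3 than at D1 (2496 of 19173), and at 4-fold or more the numbers were 832 and 159. The count fell to 669 without D1 replicate 1, 363 without D1 replicate 2, 588 without D3 replicate 1 and 1101 without D3 replicate 2. The higher genes made up 49.6% to 73.4% of the calls over the fits that leave out 1 library. Of the 40 genes named for this comparison that passed, 23 passed in each of the 8 such fits, among them Zscan4c, Duxf3, Usp17le, Cyp2b23, Serpina3m, Tgm2, Fgf4, Tcl1, Zic2, Dnmt3a, Wnt8a, Pmaip1, Atf7ip, Xaf1 and Magel2. The others missed the threshold without D1 replicate 1 (12 genes, adjusted p 0.053 to 0.12), D1 replicate 2 (14 genes, 0.056 to 0.23), D3 replicate 1 (12 genes, 0.051 to 0.31), D3 replicate 2 (7 genes, 0.05 to 0.089), D10 replicate 1 (0.054) or D10 replicate 2 (0.06). The last pair of losses was Dppa2 alone. They were Zfp352, Prdm14, Gbx2, Plk2, Gdf15, Ccne1, Ccnb2, Trib3, Gata6, Peg10, Nlrc5, Sycp1, En2, Dppa2, Dppa5a, Senp3 and Twist2.

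**Figure D1:**
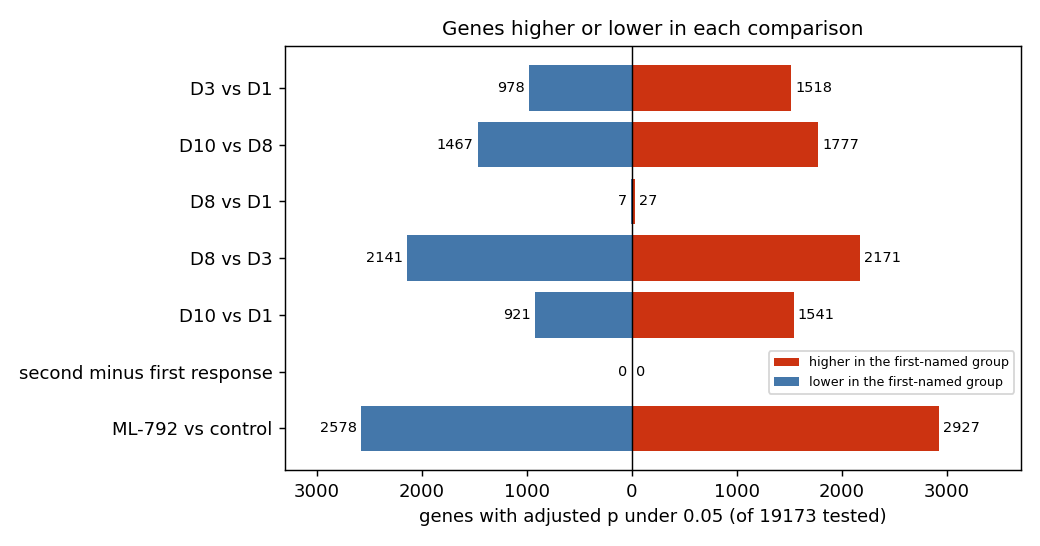
Horizontal bars give the number of genes called by edgeR (adjusted p under 0.05) in each comparison, higher to the right and lower to the left, counted from 0. ML-792 against control had the most, 2927 higher and 2578 lower, and D8 against D1 had 27 and 7.

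**Figure D2:**
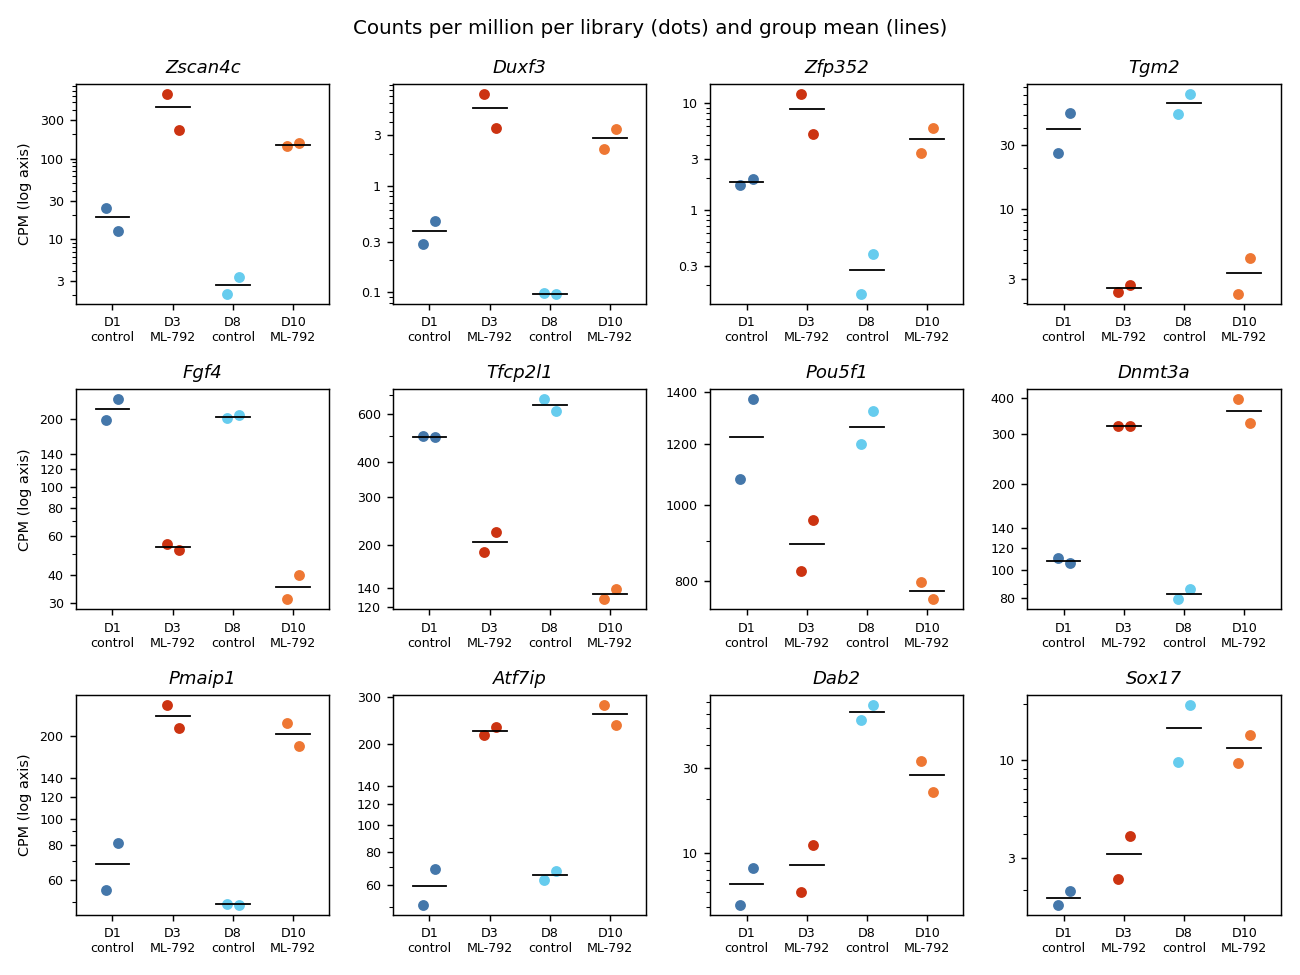
CPM on log axes for 12 genes, with a dot per library and a line at the mean of each group of 2. Zscan4c was at 18.6, 432, 2.72 and 149 CPM in the D1, D3, D8 and D10 groups, and Tgm2 at 38.8, 2.58, 61.1 and 3.34 CPM.

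D10 was compared with D8 to ask the same of the second exposure. The 2-cell-like genes rose again. Zscan4c went from 2.72 ± 0.886 to 149 ± 9.43 CPM (5.78 ± 0.57, adjusted p = 0.0011), Zscan4d rose by 6.3 ± 0.7, Duxf3 by 4.82 ± 0.58, and the single-copy genes Zfp352 by 4.05 ± 0.58 and Spz1 by 5.93 ± 0.7. The acetyltransferase-like gene Nat8f2 rose by 6.3 ± 0.51 and the claudin gene Cldn10 by 7.18 ± 0.69. Pou2f3 fell by 5.04 ± 0.49 on the log2 scale and Tgm2 by 4.16 ± 0.4. Of the 36 genes of the 2-cell-like list, 35 rose (36 adjusted over the list alone), with a median of 4.41 (camera adjusted p = 3e-22, and 0.52 with an estimated correlation). Of the 23 naive pluripotency genes 15 fell and 0 rose (17 and 2 adjusted over the list alone), with a median of -0.77 (6.6e-08, and an adjusted p of 0.41 with an estimated correlation). Fgf4, on chromosome 7 from 144847367 to 144865243, changed by -2.52 ± 0.17, Tfcp2l1, a naive-state transcription factor gene, by -2.27 ± 0.14 (645 ± 45.5 to 133 ± 8.21 CPM), Tcl1 by -2.58 ± 0.27 and Prdm14 by -2.22 ± 0.29. Here Nanog (-0.96 ± 0.24, adjusted p = 0.027) and Pou5f1 (-0.7 ± 0.15, adjusted p = 0.018) passed, and Sox2 (0 ± 0.16) did not. General pluripotency had 1 higher and 4 lower of 24, with Dppa5a at -1.88 ± 0.23 and Dppa2 at 1.39 ± 0.15.

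Of 30 p53 targets, 11 rose and 1 fell between D8 and D10 (14 and 1 adjusted over the list alone, camera adjusted p = 0.00076, and 0.83 with an estimated correlation), with Pmaip1 at 2.06 ± 0.21, Plk2 at 1.44 ± 0.3 and Gdf15 at -1.46 ± 0.27. Cell cycle genes had 5 lower and 0 higher of 34 (4 and 0 adjusted over the list alone, 0.0038, and an adjusted p of 0.52 with an estimated correlation), with Cdt1 at -0.88 ± 0.15 and Ccnb2 at -0.75 ± 0.14. The interferon response had 7 lower and 2 higher of 29 (8 and 2 adjusted over the list alone, 0.0088, and an adjusted p of 0.78 with an estimated correlation), with Xaf1 at -3.47 ± 0.4 and Ifitm1 at -3.06 ± 0.36. Imprinted genes had 11 higher and 2 lower of 46 (12 and 2 adjusted over the list alone, 0.016, and an adjusted p of 0.52 with an estimated correlation), with Magel2 at 2.54 ± 0.47 and Asb4 at 2.38 ± 0.43. The interferon call was lost without D8 replicate 2 (adjusted p = 0.11) and the imprinted call without D10 replicate 2 (0.13). Formative and primed epiblast was not called as a list (0.16) and had 6 higher and 0 lower of 18, with Dnmt3a at 2.12 ± 0.14, Zic2 at 2.47 ± 0.22 and Wnt8a at 3.69 ± 0.44. Atf7ip rose by 1.98 ± 0.17. In the SUMO pathway Senp7 rose by 1.72 ± 0.27 and Desi2 by 0.48 ± 0.13, and Uba2 (0.03 ± 0.13) and Sae1 (-0.07 ± 0.15) did not pass. Of the endoderm genes 1 of 27 rose, Fgfr2 (1.26 ± 0.23), and 1 fell, the endocytic adaptor gene Dab2 (-1.18 ± 0.32), while Sox17 (-0.35 ± 0.37) did not pass. Germline genes had 9 higher and 2 lower of 40, with Sycp1 at 1.91 ± 0.26 and Mael at 1.73 ± 0.31, and Hox genes 4 higher of 19, with Hoxa5 at 2.64 ± 0.43. Nupr1 fell by 1.56 ± 0.35, and among fibroblast markers, with 2 higher and 1 lower of 15 (0.86), Pdgfrb fell by 1.73 ± 0.34 and Fbn1 rose from 10.8 ± 0.287 to 23.8 ± 3.57 CPM. Blood and endothelial markers (0 of 11, adjusted p = 0.68) held no called gene by edgeR.

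Between D8 and D10, 1777 genes were higher and 1467 lower (3244 of 19173 by edgeR). Fold changes fell with GC content across genes (rho = -0.45), and D8 replicate 2 stood apart in that trend. The count was 1802 without D8 replicate 2, 1407 without D10 replicate 1 and 1980 without D10 replicate 2. The higher genes made up 50.8% to 71.4% of the calls over the fits that leave out 1 library, and 49.2% with the stricter filter (1092 higher and 1126 lower). Of 40 named genes that passed, 31 passed in each of the 8 fits that leave out 1 library. The other 9 were Ccnb2, Dab2, Desi2, Fbn1, Nanog, Nupr1, Pdgfrb, Plk2 and Pou5f1. Of these, 5 missed the threshold without D8 replicate 2 (adjusted p 0.052 to 0.13), 7 without D10 replicate 1 (0.062 to 0.16) and 6 without D10 replicate 2 (0.053 to 0.15). Further losses came without D1 replicate 1 (Desi2 at 0.075), D1 replicate 2 (Nanog at 0.051 and Desi2 at 0.063), D3 replicate 1 (Desi2 at 0.085), D3 replicate 2 (Desi2 at 0.072) and D8 replicate 1 (Nupr1 at 0.05). With the correction for GC content and length, added after the data were seen, Pou5f1 (-0.38, adjusted p = 0.093) and Desi2 (0.22, adjusted p = 0.25) did not pass.

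The responses to both exposures were set side by side. Of the genes called at the first exposure, 1182 were higher in both, where chance would give 141, and 730 were lower in both, where chance would give 74.8, while 1 gene, Gm4617, was called in opposite directions. Together 1912 genes, or 76.6% of those called at the first exposure, were called in the same direction at the second. They include Zscan4c, Duxf3, Zfp352, Fgf4, Tcl1, Tgm2, Dnmt3a, Pmaip1, Plk2 and Atf7ip. Across all 19173 genes the log2 fold changes correlated at r = 0.839 (rho = 0.752), with no library shared between both comparisons, and genes are not independent replicates. The number of shared calls of the first and second exposure was 631 without D1 replicate 1, 331 without D1 replicate 2, 541 without D3 replicate 1, 958 without D3 replicate 2 and 1132 without D10 replicate 1. Camera called 6 of the 22 lists for the difference between both responses, each at an adjusted p of 0.77 with an estimated correlation. Under fry each of these calls was lost, at an adjusted p of 0.65 for naive pluripotency and 0.79 for the others. Naive pluripotency (median -0.32, adjusted p = 0.00011, and a median of -0.21 without D10 replicate 1) was the call among them that held in each fit that leaves out 1 library. The gene-level test of that difference called 0 genes by edgeR, with 575 at an unadjusted p under 0.05 and 3 by DESeq2. Zscan4c (1.23 ± 0.68), Duxf3 (1.02 ± 0.8), Zfp352 (1.81 ± 0.75), Pou5f1 (-0.24 ± 0.22), Nanog (-0.2 ± 0.33), Sox2 (-0.1 ± 0.23), Sox17 (-1.12 ± 0.56), Uba2 (0.11 ± 0.18) and Sae1 (-0.14 ± 0.22) each had an adjusted p of 1. On simulated data with 200 genes changed, that test recovered 0% of genes changed 2-fold and 42.4% of those changed 4-fold. Smaller differences could therefore be missed at this depth and number of libraries.

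**Figure D3:**
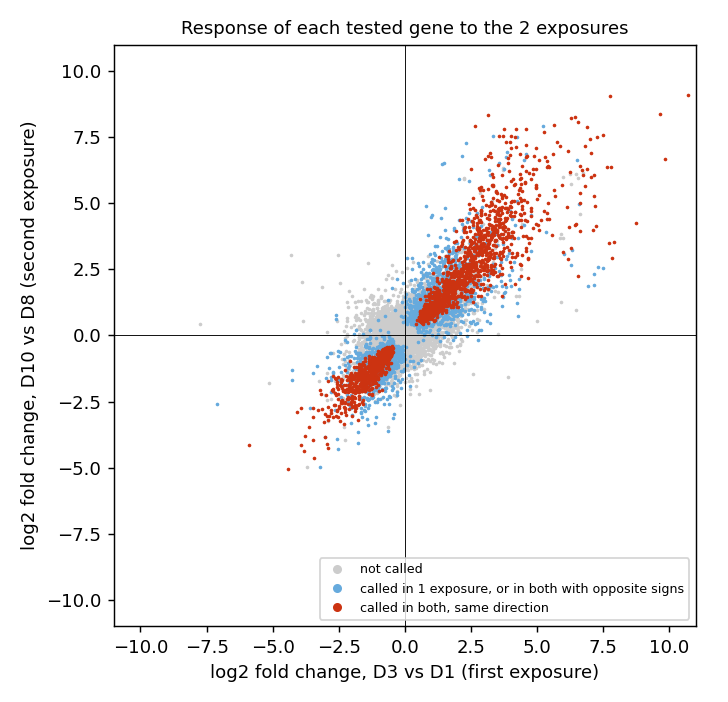
Each point is 1 of the 19173 genes tested, with the log2 fold change of D3 against D1 on the x axis and of D10 against D8 on the y axis. The 1912 genes called in both with the same direction are red, other called genes blue and the rest grey, and the points lie along the diagonal (r = 0.839 across genes).

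D8 was compared with D1 to see how control cells differed 5 days after the first exposure had ended. The labels of these 8 libraries name no culture at D8 that was never exposed, so the earlier exposure and the days in culture change together. Genes of the primitive endoderm were higher at D8. Dab2 went from 6.69 ± 2.22 to 61.5 ± 8.71 CPM (3.19 ± 0.35, adjusted p = 0.041). The endocytic receptor gene Cubn rose by 3.25 ± 0.42, the transcription factor genes Gata4 by 3.01 ± 0.44, Sox17 by 3.01 ± 0.42 and Foxq1 by 3.39 ± 0.48, Pdgfra by 2.59 ± 0.26, and Habp2, which encodes a plasma protease, by 3.48 ± 0.41. Dab2 (ENSMUSG00000022150) lies on chromosome 15 from 6299788 to 6440712, and Gata4 (ENSMUSG00000021944) on chromosome 14 from 63198922 to 63271692. Lower at D8 were the myosin gene Myo1f (-2.03 ± 0.28), the zinc finger genes Zfp600 (-1.97 ± 0.26) and Zfp981 (-0.97 ± 0.12, of a multi-copy family), the autophagy gene Gabarapl2 (-1.02 ± 0.13) and Dppa2 (-1.08 ± 0.15), a gene of pluripotent cells. These were among 27 genes higher and 7 lower (34 of 19173 by edgeR, 2311 at an unadjusted p under 0.05), and DESeq2 called 429. Pou5f1 (0.04 ± 0.15), Nanog (-0.54 ± 0.24), Sox2 (0.21 ± 0.16), Uba2 (-0.23 ± 0.13) and Sae1 (0.18 ± 0.15) did not pass. The count was 0 without D1 replicate 1, D1 replicate 2, D8 replicate 2 or D10 replicate 1, 11 without D3 replicate 1, 12 without D3 replicate 2, 4 without D10 replicate 2 and 339 without D8 replicate 1. In the first 4 of these fits, 933, 2164, 1331 and 2266 genes had an unadjusted p under 0.05. The 12 named genes that passed reached adjusted p 0.52 to 0.72 without D1 replicate 1, 0.2 to 0.24 without D1 replicate 2, 0.16 to 0.17 without D8 replicate 2 and 0.051 to 0.066 without D10 replicate 1. Of these, 9 missed the threshold without D3 replicate 1 (0.065 to 0.082), D3 replicate 2 (0.06 to 0.083) or D10 replicate 2 (0.057 to 0.07). Fold changes rose with GC content across genes (rho = 0.55), with D8 replicate 2 apart in that trend, and after the correction for it Zfp981 did not pass (-0.47, adjusted p = 0.56).

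Of the 27 primitive and extraembryonic endoderm genes, 8 rose between D1 and D8 and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.93 (camera adjusted p = 4e-22, and 0.65 with an estimated correlation). Under fry, that call and every other list call of this comparison was lost (adjusted p 0.15 to 0.45). The 2-cell-like genes lay lower. Of 36, 0 passed over all genes by edgeR and 30 were lower adjusted over the list alone, with a median of -2.36 (1.1e-22, and an adjusted p of 0.65 with an estimated correlation). Zscan4c (-2.76 ± 0.53, adjusted p = 0.11), Duxf3 (-1.95 ± 0.7, 0.33) and Zfp352 (-2.71 ± 0.59, 0.16) are among them, and DESeq2 called Zscan4c (0.0013) and Zfp352 (0.00055). Trophoblast genes had 0 of 24 over all genes and 11 higher and 1 lower adjusted over the list alone (median 0.97, adjusted p = 1.4e-05), and germline genes had 0 of 40 and 4 lower adjusted over the list alone (median -0.36, 4.3e-05), each at an adjusted p of 0.65 with an estimated correlation. Without D8 replicate 2 those medians were 0.41 and -0.54. Signalling read-outs (median 0.29, 0.0021, with 4 higher adjusted over the list alone), p53 targets (0.24, 0.011) and the interferon response (0.34, 0.014) were called as lists with 0 members over all genes, each at an adjusted p of 0.73 with an estimated correlation. Those calls were lost without D8 replicate 2 (adjusted p = 0.5, 0.21 and 0.38), where the medians were -0.02, 0.16 and 0.19. Without D1 replicate 1 the calls of p53 targets (0.6, median 0.04) and the interferon response (0.064, median 0.21) were lost, and the signalling median was 0.19. Other single libraries raised the medians to 0.49 (signalling, without D8 replicate 1), 0.43 (p53 targets) and 0.52 (interferon response, both without D1 replicate 2). Fibroblast markers had a median of 0.75, or 0.58 with the gene at 0 reads set to its bound, and were not called (0.068). Their median was 0.19 without D8 replicate 2 (adjusted p = 0.73), and the list was called without D1 replicate 2 (0.039, median 1.24), D8 replicate 1 (0.012), D10 replicate 1 (0.029), D10 replicate 2 (0.028) or the low-count filter (0.0044, median 1.01). Blood and endothelial markers had a median of 0.47 (0.084), which was -0.18 without D8 replicate 2 (0.87), and were called without D1 replicate 2 (0.043) or D8 replicate 1 (0.01, median 0.69).

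**Figure D4:**
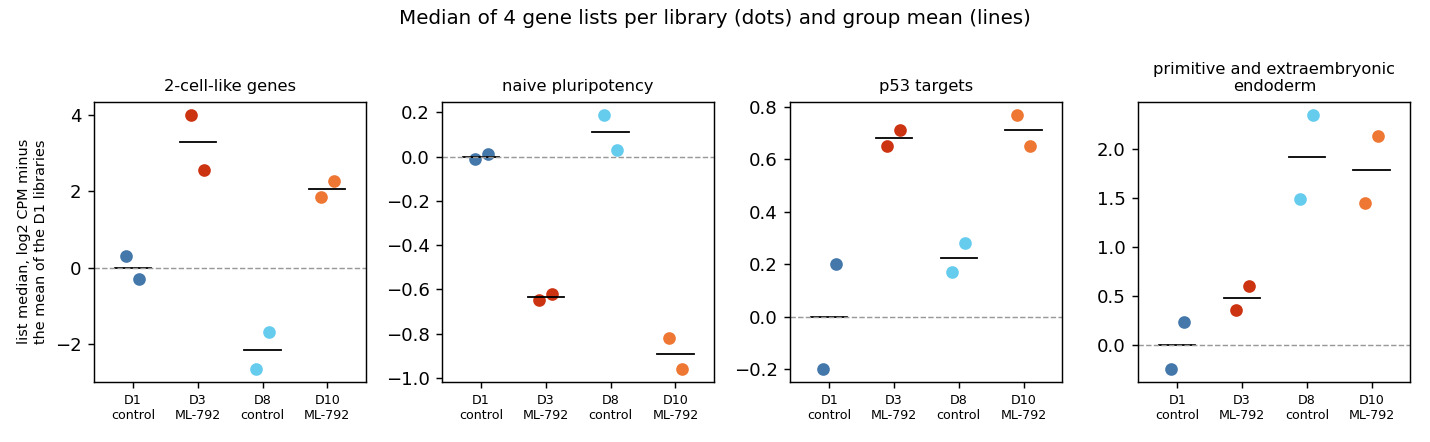
For 4 gene lists, each dot is the median over the list's genes of log2 CPM in 1 library minus the mean of the D1 libraries. The endoderm medians were 1.49 and 2.35 in the D8 libraries and 1.45 and 2.13 in the D10 libraries, against 0.36 and 0.61 at D3, while the 2-cell-like medians were 4.01 and 2.56 at D3 and -2.66 and -1.68 at D8.

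Genes called between D3 and D1 were set beside those called between D8 and D1. Of the 34 called at D8, 8 had been called in the same direction at D3 (7 higher against 2.14 by chance, 1 lower against 0.357) and 4 in the opposite direction. Those 4, named after their values were seen, were Dppa2, Zfp981, Plec and Lad1. In the fits without D1 replicate 1, D1 replicate 2, D8 replicate 2 or D10 replicate 1, edgeR called 0 genes between D8 and D1 (933, 2164, 1331 and 2266 at an unadjusted p under 0.05), so no overlap was left. Across all genes the fold changes correlated at r = -0.06. Both comparisons use the D1 libraries, and simulated groups with no change gave a mean r of 0.508 and at most 0 shared calls in 20 simulations.

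D8 was compared with D3 to follow the 5 days after the inhibitor had been withdrawn. The 2-cell-like genes fell, with log2 fold changes of -7.31 ± 0.61 for Zscan4c (adjusted p = 0.00051), -7.98 ± 0.75 for Zscan4d, -5.75 ± 0.58 for Duxf3 and -4.95 ± 0.59 for Zfp352. The metalloprotease gene Mmp1b and the kininogen gene Kng2 had 0 reads at D8 and were at least 44.3-fold and at least 42.4-fold lower. Nkx6-3 rose by 5.19 ± 0.46, Tgm2 by 4.56 ± 0.42, the circadian regulator gene Bhlhe40 by 4.05 ± 0.32 and Lad1 by 4.25 ± 0.29. All 36 genes of the 2-cell-like list fell, also adjusted over the list alone, with a median of -5.8 (camera adjusted p = 1.6e-24, and 0.52 with an estimated correlation). Of 23 naive pluripotency genes 13 rose and 1 fell (15 and 1 adjusted over the list alone, 0.00012, and an adjusted p of 0.52 with an estimated correlation), with Fgf4 at 1.94 ± 0.17, Tcl1 at 2.46 ± 0.27 and Tfcp2l1 at 1.64 ± 0.14. Pou5f1 (0.5 ± 0.15, adjusted p = 0.047) passed, and Nanog (0.22 ± 0.24) and Sox2 (0.1 ± 0.16) did not. Of 27 endoderm genes 15 rose and 1 fell (19 and 1 adjusted over the list alone, 1.7e-06, and an adjusted p of 0.52 with an estimated correlation), with Dab2 at 2.83 ± 0.35, Gata4 at 2.51 ± 0.43, Cubn at 2.31 ± 0.4 and Sox17 at 2.24 ± 0.4. Of 24 trophoblast genes 9 rose and 1 fell (12 and 2 adjusted over the list alone, 0.0015, and an adjusted p of 0.55 with an estimated correlation), with Tead4 at 2.77 ± 0.21. Of 40 germline genes 15 fell and 0 rose (17 and 2 adjusted over the list alone, 0.0089, and an adjusted p of 0.55 with an estimated correlation), with the RNA-binding protein gene Dazl at -2.34 ± 0.25 and Sycp1 at -2.41 ± 0.27. Formative and primed epiblast had 5 lower and 2 higher of 18 and was not called (0.4), with Dnmt3a at -1.94 ± 0.14 and Zic2 at -3.14 ± 0.22. Blood and endothelial markers had 3 higher and 0 lower of 11 (median 0.36, 0.4, and a median of -0.23 without D8 replicate 2), and fibroblast markers 1 higher and 2 lower of 15 (median -0.04, 0.84, and -0.98 without D8 replicate 2), and neither list was called.

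The interferon response had 9 higher and 1 lower of 29 between D3 and D8 (10 and 1 adjusted over the list alone, camera adjusted p = 0.0026, and 0.52 with an estimated correlation), with Xaf1 at 3.97 ± 0.41 and Ifitm1 at 3.1 ± 0.36. Of 30 p53 targets 12 fell and 1 rose (14 and 1 adjusted over the list alone, 0.0089, and an adjusted p of 0.71 with an estimated correlation), with Pmaip1 at -2.28 ± 0.21 and Plk2 at -1.38 ± 0.3. Cell cycle genes had 7 higher and 0 lower of 34 (6 and 0 adjusted over the list alone, 0.014), with Cdt1 at 0.85 ± 0.15 and Ccnb2 at 0.86 ± 0.14, and the integrated stress and unfolded protein response had 7 higher and 2 lower of 25, also adjusted over the list alone (0.018), both at an adjusted p of 0.52 with an estimated correlation. Atf7ip changed by -1.77 ± 0.17, the histone methyltransferase gene Ehmt2 by 0.83 ± 0.17 and Zmym2 by -0.66 ± 0.16, and Uba2 (-0.14 ± 0.13) and Sae1 (0.11 ± 0.15) did not pass. List calls were lost without D3 replicate 2 for germline genes (adjusted p = 0.1), p53 targets (0.07) and cell cycle (0.11), without D8 replicate 1 for p53 targets (0.14) and without D8 replicate 2 for the integrated stress list (0.15). In all, 2171 genes were higher and 2141 lower at D8 than at D3 (4312 by edgeR). The count was 1522 without D3 replicate 1, 1996 without D3 replicate 2 and 2579 without D8 replicate 2. The higher genes made up 50.3% of the calls, and 37.3% (without D3 replicate 1) to 56.1% (with the stricter filter) over the alternatives, among them 40.5% without D3 replicate 2 and 42.3% with the correction for GC content and length. D8 replicate 2 stood apart in GC content, and fold changes between D8 and D3 rose with GC content across genes (rho = 0.471). Of 32 named genes that passed, 26 did so in each of the 8 fits that leave out 1 library. Without D3 replicate 1, Cdt1, Ehmt2, Plk2, Pou5f1, Sox17 and Zmym2 missed the threshold (adjusted p 0.051 to 0.28). Without D3 replicate 2, 4 of these did (0.053 to 0.11), and without D8 replicate 2, Pou5f1 (0.12) and Zmym2 (0.089) did. Pou5f1 also missed it without D1 replicate 1 (0.051), D1 replicate 2 (0.056), D10 replicate 1 (0.066) or D10 replicate 2 (0.06). With the correction for GC content and length, Pou5f1 (0.12, adjusted p = 0.59) and Zmym2 (-0.19, adjusted p = 0.4) did not pass, and the germline (0.11) and integrated stress (0.087) list calls were lost. RLE size factors ended 1 of the 32 calls of named genes and kept 31.

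D10 was compared with D1 to set the end of both exposures against the start. The glutamate receptor gene Grin2a rose from 0.214 ± 0.171 to 13.8 ± 6.85 CPM (6.11 ± 0.59, adjusted p = 0.0012), Cthrc1 by 5.9 ± 0.61 and Creb5 by 5.7 ± 0.64. Pou2f3 (-5.44 ± 0.49) and the riboflavin transporter gene Slc52a3 (-3.46 ± 0.38) fell. Of 36 genes of the 2-cell-like list, 21 rose and 0 fell (33 and 0 adjusted over the list alone, median 2.1, camera adjusted p = 2.3e-11, and 0.46 with an estimated correlation), with Zscan4c at 3.01 ± 0.49, Duxf3 at 2.88 ± 0.49 and Spz1 at 3.56 ± 0.57, while Zfp352 (1.34 ± 0.48, adjusted p = 0.1, and 0.041 by DESeq2) did not pass. Of 23 naive pluripotency genes 14 fell and 1 rose (18 and 3 adjusted over the list alone, median -0.85, 9.3e-08, and an adjusted p of 0.4 with an estimated correlation), with Fgf4 at -2.64 ± 0.17, Tcl1 at -2.26 ± 0.27 and Nanog at -1.5 ± 0.24. Of 27 endoderm genes 18 rose and 0 fell (20 and 0 adjusted over the list alone, median 1.88, 6.1e-10, and an adjusted p of 0.4 with an estimated correlation), with Sox17 at 2.66 ± 0.41, Fgfr2 at 2.98 ± 0.25, Gata6 at 2.74 ± 0.26 and Foxq1 at 2.68 ± 0.48. Of 30 p53 targets 16 rose and 1 fell (23 and 1 adjusted over the list alone, 7.6e-08, and an adjusted p of 0.4 with an estimated correlation), with Plk2 at 1.99 ± 0.31, Dcxr at 1.87 ± 0.41 and Tap1 at 2.61 ± 0.42. Formative and primed epiblast had 7 higher and 0 lower of 18 (9 and 3 adjusted over the list alone, 0.0039, and an adjusted p of 0.4 with an estimated correlation), with Wnt8a at 4.24 ± 0.48 and Cdh2 at 1.81 ± 0.31. Imprinted genes had 11 higher and 1 lower of 46 (13 and 1 adjusted over the list alone, 0.036), with Peg10 at 2.08 ± 0.27 and Magel2 at 2.68 ± 0.48, and cell cycle genes 5 lower and 0 higher of 34, also adjusted over the list alone (0.0043), both at an adjusted p of 0.4 with an estimated correlation. Signalling read-outs had 8 higher and 0 lower of 26 (8 and 1 adjusted over the list alone, 0.021, and an adjusted p of 0.78 with an estimated correlation), with Dusp4 at 2.57 ± 0.35. Pdgfra rose by 3.03 ± 0.26, Atf7ip by 2.11 ± 0.17 and Senp7 by 1.76 ± 0.27. Senp3 fell by 0.97 ± 0.14, and Pou5f1 was at -0.66 ± 0.15 (adjusted p = 0.027). Sox2 (0.21 ± 0.16), Uba2 (-0.2 ± 0.13) and Sae1 (0.11 ± 0.15) did not pass, and Twist2, at 0 reads at D1, was at least 5.31-fold higher. It was among 2 higher of 15 fibroblast markers (0.21), and blood and endothelial markers had 1 higher of 11 (0.62).

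Over all genes, 1541 were higher and 921 lower at D10 than at D1 (2462 by edgeR). The count was 557 without D1 replicate 1, 559 without D1 replicate 2, 1200 without D10 replicate 1 and 1172 without D10 replicate 2. The higher genes made up 62.6% of the calls, but 47.9% without D1 replicate 1 and 74.4% without D10 replicate 1. Of 29 named genes that passed, 16 did so in each of the 8 fits that leave out 1 library, among them Grin2a, Fgf4, Tcl1, Nanog, Fgfr2, Gata6, Pdgfra, Wnt8a, Dusp4, Peg10 and Atf7ip. Without D1 replicate 1, 11 genes missed the threshold (adjusted p 0.054 to 0.15), without D1 replicate 2, 10 (0.052 to 0.19), without D10 replicate 1, Pou5f1 (0.094) and Twist2 (0.058), and without D10 replicate 2, Pou5f1, Twist2 and Dcxr (0.095 to 0.11). The others so affected were Zscan4c, Duxf3, Spz1, Sox17, Foxq1, Cdh2, Plk2, Tap1, Magel2 and Senp7. The imprinted call was lost without D1 replicate 2 (adjusted p = 0.087), without D10 replicate 2 (0.17) and with the correction for GC content and length (0.083), and the call of signalling read-outs without D10 replicate 2 (0.36). Of the 34 genes called between D8 and D1, 22 higher and 2 lower (70.6%) were called in the same direction between D10 and D1. Zfp981 was called in the opposite direction. D1 is in both comparisons, and simulated groups with no change shared at most 1 call in 20 simulations. The 34 calls fell to 0 without D1 replicate 1, D1 replicate 2, D8 replicate 2 or D10 replicate 1, and with them the overlap (933, 2164, 1331 and 2266 genes had an unadjusted p under 0.05 by edgeR in those fits).

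All 4 ML-792 libraries were compared with all 4 control libraries to describe what both exposures had in common. Neither exposure had an untreated library at its end. Cyp2b23 rose by 5.85 ± 0.32 (adjusted p = 1.6e-05, n = 4 in each group, edgeR), the protocadherin gene Pcdh8 by 5.35 ± 0.33 and Nat8f2 by 5.36 ± 0.54, and Tgm2 fell by 4.06 ± 0.32. All 36 genes of the 2-cell-like list rose, also adjusted over the list alone (median 3.77, camera adjusted p = 7.7e-15, and 0.54 with an estimated correlation), with Zscan4c at 4.79 ± 0.81, Duxf3 at 4.12 ± 0.54, Zfp352 at 2.67 ± 0.66 and Spz1 at 4.79 ± 0.62. Of 23 naive pluripotency genes 15 fell and 2 rose (17 and 2 adjusted over the list alone, 5.2e-06, and an adjusted p of 0.3 with an estimated correlation), with Fgf4 at -2.26 ± 0.17, Tcl1 at -2.37 ± 0.19, Tfcp2l1 at -1.75 ± 0.19 and Nanog at -0.84 ± 0.25. Pou5f1 changed by -0.57 ± 0.11 (adjusted p = 0.0035), and Sox2 (0.05 ± 0.12) and Sox17 (-0.17 ± 0.76) did not pass. Of 30 p53 targets 17 rose and 1 fell (21 and 1 adjusted over the list alone, 1.3e-05, and an adjusted p of 0.54 with an estimated correlation), with Pmaip1 at 1.91 ± 0.18 and Plk2 at 1.66 ± 0.23. Cell cycle genes had 9 lower and 0 higher of 34, also adjusted over the list alone (0.0016, and an adjusted p of 0.3 with an estimated correlation), with Ccne1 at -0.8 ± 0.11. The interferon response had 10 lower and 2 higher of 29 (10 and 3 adjusted over the list alone, 0.022, and an adjusted p of 0.63 with an estimated correlation), with Xaf1 at -3.53 ± 0.3. Imprinted genes had 12 higher and 2 lower of 46, also adjusted over the list alone (0.026, and an adjusted p of 0.3 with an estimated correlation).

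Outside the called lists, Dnmt3a rose by 1.83 ± 0.13, Atf7ip by 1.94 ± 0.12 and Senp7 by 1.38 ± 0.26 in the ML-792 libraries, and the SUMO ligase gene Pias4 (-0.41 ± 0.13), Ehmt2 (-0.53 ± 0.14) and the serine synthesis gene Psat1 (-0.89 ± 0.1) fell. Uba2 (-0.03 ± 0.098, adjusted p = 0.83) and Sae1 (0 ± 0.11, adjusted p = 0.99) did not pass. In all, 2927 genes were higher and 2578 lower (5505 by edgeR), and the higher genes made up 47.6% (without D1 replicate 1) to 57.2% of the calls over the fits that leave out 1 library, 47.6% with the stricter filter and 49.8% with the most abundant genes left out. Fibroblast markers had 3 higher and 1 lower of 15 (adjusted p = 0.41), and blood and endothelial markers 1 higher and 3 lower of 11 (0.91). Of 23 named genes that passed, 20 did so in each of the 8 fits that leave out 1 library. Nanog missed the threshold without D1 replicate 1 (0.064), D1 replicate 2 (0.083) or D10 replicate 2 (0.063), Ehmt2 without D3 replicate 2 (0.057), and Pias4 without D1 replicate 2 (0.089), D3 replicate 1 (0.079), D3 replicate 2 (0.087), D8 replicate 1 (0.053) or D10 replicate 1 (0.11). The interferon response was not called without D8 replicate 2 (adjusted p = 0.12), and imprinted genes were not called without D10 replicate 2 or without the low-count filter (0.052 each). With the correction for GC content and length, Pou5f1 (-0.31, adjusted p = 0.059), Pias4 (-0.14, adjusted p = 0.23) and the imprinted list (0.06) did not pass.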

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

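The tests of other lineages, of days in culture, of single-copy members and of splits that keep the days whole, and the correction for GC content and length, were chosen after the results had been seen. Within the 4 libraries of a treatment class, 1 library lay far from the other 3 in 3 of 72 sets of values examined, and chance gives about 1 in 20. Nat8f2 was at 5.27 log2 CPM in D3 replicate 1, against 3.87 to 4.07 in the other ML-792 libraries. Dnmt3a was at 8.63 log2 CPM in D10 replicate 1, against 8.31 to 8.35. The share of reads from Eef2 was 0.315% in D10 replicate 2, against 0.257% to 0.264%.

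Camera called 6 lists for the difference between the second and the first response, each at an adjusted p of 0.77 with an estimated correlation and with no gene called over all genes by edgeR (575 at an unadjusted p under 0.05, 3 by DESeq2). Under fry each of these list calls was lost (adjusted p 0.65 to 0.79). The 2-cell-like genes had a median of 0.83 (camera adjusted p = 3.2e-06). Relative to D1, the list medians per library were 4.01 and 2.56 at D3, -2.66 and -1.68 at D8, and 1.84 and 2.28 at D10. The larger rise at the second exposure thus began at a lower level and ended at a lower one. Its call was lost without D3 replicate 2 (median 0.32) or D8 replicate 1 (median 0.62). Without D1 replicate 1, D3 replicate 1 or D8 replicate 2 the call stayed, at a median of 0.53, 1.86 or 1.53. Naive pluripotency had a median of -0.32 (0.00011), and -0.21 without D10 replicate 1 (0.0028). Primitive and extraembryonic endoderm had a median of -0.76 (3.2e-06), which was -0.02 without D8 replicate 2, where the call was lost. It was -1.24 without D8 replicate 1 and -0.44 without D10 replicate 1. Relative to D1, the medians of replicates 1 and 2 were -0.24 and 0.24 at D1, 0.36 and 0.61 at D3, 1.49 and 2.35 at D8, and 1.45 and 2.13 at D10. Replicate 2 was higher in each group, so leaving out 1 library also unbalances the replicates. Whether the difference rests on 1 library cannot be told. The integrated stress and unfolded protein response had a median of 0.18 (0.047), lost without D1 replicate 1 (0.23), D3 replicate 1 (0.15), D8 replicate 1 (0.6), D10 replicate 1 (0.056) or D10 replicate 2 (0.13), with medians of 0.12 to 0.32 over the fits that leave out 1 library. Signalling read-outs had a median of -0.31 (0.039), lost without D1 replicate 1 (0.23, median -0.2), D3 replicate 1 (0.11, median -0.39), D8 replicate 2 (0.77) or D10 replicate 1 (0.63). The median was 0.03 without D8 replicate 2, with its sign turned, -0.07 without D10 replicate 1, -0.59 without D8 replicate 1 and -0.64 without D10 replicate 2. Fibroblast markers had a median of -0.73 (0.048), lost without D1 replicate 1 (0.37, median -0.58), D3 replicate 1 (0.15, median -0.79), D8 replicate 2 (0.58, median -0.18) or D10 replicate 1 (0.57, median -0.32). It was -1.1 without D1 replicate 2 and -1.26 without D10 replicate 2.

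The primitive and extraembryonic endoderm list had a median log2 fold change of 1.93 at D8 against D1, with Dab2, Gata4 and Sox17 among its members. A single D8 library as the source is argued against by the lower of the medians without each D8 library, 1.54, and a trend with GC content or gene length by the median after the correction, 1.73. A rise of every lineage alike is argued against by the primitive streak and mesoderm list, with a median of -0.03 (quartiles -0.34 and 0.96), and the neural ectoderm list, at 0.36 (-0.24 and 0.53), against endoderm quartiles of 1.58 and 2.79. Over the fits that leave out 1 library, those medians ran from -0.21 to 0.31 and from 0.03 to 0.53, and the endoderm median from 1.54 to 2.38, each lowest without D8 replicate 2 and highest without D1 replicate 2. The trophoblast list lay between, at 0.97 (0.34 and 1.92, and a median of 0.41 without D8 replicate 2), as did fibroblast markers, at 0.75 (0.26 and 1.69, and a median of 0.19 without that library), and blood and endothelial markers, at 0.47 (0.03 and 0.9, and -0.18 without it). Smaller rises of those lists beside the endoderm list stay open. Days in culture and the earlier exposure cannot be told apart, since the labels name 0 libraries after D1 from cells that were never exposed. A lasting effect of the first exposure is a candidate explanation that these libraries do not test.

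The 2-cell-like list had a median of -2.36 at D8 against D1, below the level before any exposure, although 0 of its 36 genes passed over all genes by edgeR. A single D1 library as the source is argued against by the higher of the medians without each D1 library, -1.99, and a trend with GC content or gene length by the median after the correction, -2.07. Reads shared between near-identical copies are argued against by the genes outside multi-copy families, Zfp352 (-2.71), Tmem92 (-2.39), Spz1 (-2.37) and Arg2 (-2.1), with a median of -2.38. Whether a culture kept for the same days without ML-792 would show the same level stays open, and a lower share of cells in the 2-cell-like state may be one source.

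More genes had reads in the ML-792 libraries, 28012 to 29331, than in the control libraries, 25579 to 26571. Library depth is argued against by thinning each library to 21040992 reads, after which the lowest ML-792 library still had 1373 more genes with reads than the highest control library. Of the 6901 genes with a mean of 5 to 50 reads, 58.5% were higher in ML-792 libraries. That argues against a diffuse background strong enough to raise nearly all genes at that level. By class the share was 59% of 3034 coding genes, 58% of 598 lincRNAs, 49.3% of 1156 processed pseudogenes and 84.2% of 95 unprocessed pseudogenes. A weaker or sparser background could add genes with few reads and raise only a part of the genes at that level, so it stays open. Genes with at least 10 reads after thinning numbered 16952 to 17220 in ML-792 libraries and 15984 to 16485 in control libraries. Transcription from otherwise silent genes under ML-792 may account for the higher number of genes with reads, a hypothesis found in these data and not tested apart from them.

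The 8 libraries can be split into 4 and 4 in 35 ways, and 1 of them, the real one, called as many genes as ML-792 against control (5505, against at most 4 in the others). Of these splits 32 part the libraries of at least 1 day, so they say nothing of how whole days would group by chance. The splits that keep the libraries of each day together number 3, too few for a share under 0.05, and the real one called 5505 genes and the higher of the others 4.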

How the results depend on the processing

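The correction for GC content and length was chosen after seeing the data, and the other alternatives before. No named gene that was called changed sign. Among called lists, the median of signalling read-outs changed sign without D8 replicate 2, where the call was lost, from 0.29 to -0.02 (D8 against D1) and from -0.31 to 0.03 (second minus first response). The balance of higher and lower genes turned with the stricter filter for D10 against D8 (1092 higher, 1126 lower) and ML-792 against control (1775, 1955), without D1 replicate 1 for D3 against D1 (332, 337), D10 against D1 (267, 290) and ML-792 against control (2629, 2890), with the most abundant genes left out for the last (2802, 2822), and in most alternatives for D8 against D3. Counts of called genes stayed within 1.5 times for each comparison with RLE size factors and with the most abundant genes left out. Without the low-count filter they were 3847 (D3 against D1), 973 (D8 against D1), 3775 (D10 against D1) and 66 (second minus first response). With the stricter filter, D8 against D1 had 0 by edgeR, with 1790 at an unadjusted p under 0.05 and 429 by DESeq2 without that filter. With replicate number as a block they were 4187 (D3 against D1), 5298 (D10 against D8), 535 (D8 against D1), 6547 (D8 against D3) and 4100 (D10 against D1), with 3179 shared calls of the first and second exposure. With that block Zscan4c (adjusted p = 0.015) and Zfp352 (0.045) were called between D8 and D1, and Nanog (0.03) and Pou5f1 (0.028) between D3 and D1. The replicate differences of the groups correlated across genes at 0.1 to 0.5. With only the groups compared in the fit they were 4063 (D3 against D1), 1465 (D10 against D8) and 3 (D8 against D1). DESeq2 called 429 (D8 against D1) and 3 (second minus first response), and the GC correction 79 (D8 against D1). For the changes without the filter, with the block, with only the groups compared, with DESeq2 and with the correction, the cause was not tested. By construction fewer genes passed an adjusted p under 0.01: 772 (D3 against D1), 1043 (D10 against D8), 0 (D8 against D1, 2311 at an unadjusted p under 0.05), 1809 (D8 against D3), 709 (D10 against D1) and 2924 (ML-792 against control), or a 2-fold minimum, 2942 (ML-792 against control). Leaving out each library gave 363 to 3209 genes (D3 against D1), 1407 to 4326 (D10 against D8), 0 to 339 (D8 against D1), 1522 to 5826 (D8 against D3), 557 to 3244 (D10 against D1) and 331 to 1970 (shared calls). The 0 for D8 against D1 was by edgeR without D1 replicate 1, D1 replicate 2, D8 replicate 2 or D10 replicate 1, where 933, 2164, 1331 and 2266 genes had an unadjusted p under 0.05. Over all alternatives, 95 counts by direction moved by over 1.5 times and 155 did not. Of the values of named genes, 2322 kept their direction and their side of the threshold, 205 lost the call, 11 gained it and 42 changed sign without a call in either setting. For gene lists the numbers were 1861, 130, 67 and 98. An estimated correlation, a setting not tried on the simulated lists, ended all 50 list calls. Fry tests a list against no change, where camera tests it against the other genes. Under fry, 21 list calls were lost and 14 gained. Those lost include every list called for D8 against D1 (adjusted p 0.15 to 0.45, with the endoderm list at 0.15 and the 2-cell-like list at 0.24). They also include every list called for second minus first response (0.65 to 0.79) and the 2-cell-like list for D10 against D1 (0.07). Simulated 2-fold changes were recovered in 14.9% to 35.8% of genes in comparisons of 2 groups, with 200 genes changed. Each of these comparisons except D8 against D1 called far more genes than that, so its recovery may differ. A missing call does not show that a gene was unchanged.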

Other observations

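The genome regions and gene families given here were chosen after the data had been seen. A cluster of zinc finger genes on chromosome 4 held 72 tested genes, of which 24 rose and 1 fell between D1 and D3, and 33 rose and 1 fell between D8 and D10, against 7.92% and 9.27% of all genes higher. In it, Platr16, a noncoding RNA gene, rose by 2.44 ± 0.29 (SE) at D3, Zfp981 (chromosome 4, 146502027 to 146539395) by 1.17 ± 0.12 and Zfp978 by 1.06 ± 0.27. The cluster's median log2 fold changes were 0.9 at the first exposure and 1.32 at the second. Over the fits that leave out 1 library, the first ran from 0.77 (without D3 replicate 1) to 1.04 (without D3 replicate 2). The second ran from 0.94 (without D8 replicate 2) to 1.86 (without D8 replicate 1). At D8 against D1 the cluster had a median of -0.81, with 60 of the 72 genes below 0. That median was -0.4 without D8 replicate 2 (51 below 0), -1.3 without D8 replicate 1 and -0.56 after the correction for GC content and length. Zfp600 and Zfp981 were called lower at D8, and both calls were lost in each fit that leaves out 1 library other than D8 replicate 1 (adjusted p 0.054 to 0.52). After the correction Zfp981 did not pass (-0.47, adjusted p = 0.56). A cluster on chromosome 12 between 87 and 89 Mb had 32 and 30 of 49 genes higher at the first and the second exposure. Its medians were 3.45 and 4.09. Over the fits that leave out 1 library, they ran from 2.25 (without D3 replicate 1) to 4 and from 3.88 to 4.09. The Zscan4 cluster on chromosome 7 between 10 and 12 Mb had 12 and 13 of 14, with medians of 4.37 and 5.75. Over those fits they ran from 3.44 (without D3 replicate 1) to 5.01 and from 5.4 to 6.02. The Pramel cluster on chromosome 4 had 11 and 12 of 25, with medians of 1.19 and 1.11. The first ran from 0.43 (without D1 replicate 1) to 1.83 (without D1 replicate 2). The second ran from 0.55 (without D8 replicate 1) to 1.58 (without D8 replicate 2). In each cluster, as over all genes, fewer genes were called at the first exposure without D1 replicate 1 or without D1 replicate 2. These clusters hold near-identical copies, so the reads of single members are uncertain.

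Among gene families, 11 of 23 olfactory receptor genes and 10 of 16 vomeronasal receptor genes rose between D1 and D3, and at most 4 and 3 without D1 replicate 1, D1 replicate 2 or D3 replicate 1. Between D8 and D10, 15 and 11 rose, with 8 and 3 without D8 replicate 2 and 11 and 6 without D10 replicate 1. Their median levels over all libraries were 0.702 and 0.359 CPM. Of all 14693 coding genes tested, 7.72% were higher and 6.21% lower at the first exposure, and 9.22% and 9.43% at the second. Calls over all genes at the first exposure also fell without D1 replicate 1, D1 replicate 2 or D3 replicate 1. Histone genes had 17 of 64 lower between D8 and D10, and from 3 (without D10 replicate 1) to 49 (without D8 replicate 1) over the fits that leave out 1 library, with 6 without D8 replicate 2. PolyA selection would have left out most of their transcripts, and their median level of 262 CPM over all libraries argues against its use. The Klf genes, which include regulators of naive pluripotency, had 4 of 17 lower and 2 higher at the first exposure, with at most 1 of each without any 1 of the D1 and D3 libraries. At the second they had 7 lower and 1 higher, with 3 lower without D10 replicate 1. Unprocessed pseudogenes rose in 31.4% of 118 and 38.1% at the first and second exposure. The first share was at most 7.63% without D1 replicate 1, D1 replicate 2 or D3 replicate 1 and 20.3% without D3 replicate 2, and the second 18.6% without D8 replicate 2 and 22% without D10 replicate 1. LincRNAs rose in 17% of 702 and 18.1%. The first share was at most 3.99% without D1 replicate 1, D1 replicate 2 or D3 replicate 1 and 11% without D3 replicate 2. The second was 7.55% without D8 replicate 2, 10.5% without D10 replicate 1 and 11.3% without D10 replicate 2.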
